A study of Mus musculus with 9 samples.

How the data were processed

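RNA sequencing measured mRNA in 9 libraries of MH-S cells, a mouse alveolar macrophage cell line, in 3 groups of 3. Per the labels, the CON group received culture medium, and the LPS group received 1 µg/ml lipopolysaccharide, a bacterial outer membrane component that activates the receptor TLR4, for 4 h. The third group, SUR, is labelled suramin, a polyanionic drug. Its treatment protocol describes 200 µM suramin only together with 1 µg/ml LPS for 4 h, so SUR is treated here as suramin with LPS; the sample labels themselves name suramin without LPS. Libraries were made from total RNA extracted with Trizol, using the MGIEasy RNA Library Prep Kit, per the labels' protocols. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

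Per the submitters' processing notes, the authors used HISAT2 2.0.4 and the mouse genome build GRCm38 (mm10). The tool that counted reads and the annotation release are not given in the sources used here. The deposited expected counts are estimated reads per gene without normalization, per the file headers and the values. Of the count values, 93.4% were whole numbers (no remainder), and all were rounded to whole numbers before testing. The deposited FPKM values are scaled by the authors for transcript length and library size, per the file headers. The deposited TPM values are in the authors' length- and depth-scaled unit, and their column sums lay between 999999 and 1000001; they served only to check the table. The authors' log2 fold changes and DESeq2 q-values for the 3 comparisons, named in the file headers, were read only to compare totals, and their DESeq2 version and settings are not given in the sources used here. The table held 14771 genes, all typed as mRNA, each with a count in at least 1 library. It held 0 of the mitochondrially encoded mRNAs, so the mitochondrial share of reads, a sign of RNA quality, was not analysed here.

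Library totals ran from 15729402 to 16675250 counts. Genes were kept by edgeR's filterByExpr, which left 11281 genes tested and 3490 not tested; at least 99.965% of each library's counts fell in tested genes. Libraries were scaled by TMM (factors 0.934 to 1.04). The test was edgeR 4.0.16's quasi-likelihood F test (R 4.3.3) with all 9 libraries in 1 fit, a mean per group and no covariate, and Benjamini-Hochberg adjustment over the tested genes at a threshold of 0.05. Each gene's dispersion was shared by the 3 groups, so the spread among CON libraries also enters the p-values of SUR against LPS. Levels are CPM, counts scaled to a common library size with TMM, given as mean ± SD of 3 libraries. Standard errors of log2 fold changes were derived from the F statistic. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

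The groups, the tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule always names Nlrp3, Pycard, Casp1, Casp4, Gsdmd, Il1b and Il18. It adds, per comparison, the 8 largest rises and the 8 largest falls in log2 fold change among called genes with a mean log2 CPM of at least 4 and no overlap between the 2 groups' libraries, leaving out predicted gene models. It also allows up to 4 called members of each described list, those with the largest changes, and the 8 genes per direction that moved back most in SUR. Genes named outside the rule are marked as chosen after their values were seen. Genes of families with near-identical copies (Gbp2 and Gbp5 among those named) are uncertain, since the authors' counting could split or share such reads.

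The 29 gene lists covered inflammasome and pyroptosis genes, cytokines and chemokines, NF-kappaB targets and feedback genes, interferon-stimulated genes, TLR4 signalling components, immediate-early and MAPK feedback genes, purinergic receptors and ectonucleotidases, growth factors and receptors, alveolar macrophage genes, alternative activation genes, sterol biosynthesis and uptake, LXR and lipid efflux genes, glycolysis and hypoxia genes, lysosome genes, NRF2 targets, unfolded protein and integrated stress response genes, heat shock genes, apoptosis and p53 targets, necroptosis and ferroptosis genes, cell cycle genes, coagulation and fibrinolysis genes, antigen presentation genes, endocytosis and scavenger receptors, nuclear genes of oxidative phosphorylation, housekeeping genes, mitochondrially encoded mRNAs, and markers of epithelial cells, of fibroblasts and endothelium, and of lymphocytes and neutrophils. Members past the threshold were counted with adjustment over all tested genes and with adjustment over the list alone. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated per list.

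Replicate numbers are shared between groups, and whether they pair the samples was checked before any calls were compared. Deviations from the group mean correlated at 0.435 to 0.801 in the 9 pairs of libraries with the same number and at -0.643 to 0.437 in the 18 pairs with different numbers. In 9 of 9 libraries the best match in another group had the same number, so the numbers were taken to pair the samples. This pairing comes from the data and no label states it. The libraries numbered 1 stood furthest apart, and margins between numbers 2 and 3 were smaller. CON 3 correlated at 0.447 with SUR 3 and 0.421 with SUR 2, and LPS 3 at 0.586 with SUR 3 and 0.437 with SUR 2. The fit with the replicate number as a block is given beside a printed gene or list whose call it changed, and beside a printed count that it moved by more than 1.5 times. No library repeated another of its group: chi-square per gene, near 1 for repeated sampling of the same library, was lowest, at 3.75, between SUR 2 and SUR 3.

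Alternatives were relative log expression and upper-quartile scaling, other filters on low counts, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1), only the 6 libraries compared, the replicate block, a threshold of 0.01, a test against a 1.5-fold change (edgeR's glmTreat), and leaving out each library in turn. Added after seeing the data were fits without the 3 libraries numbered 1, the replicate block without CON 1, and tests of the KEGG pathways named in the deposited annotation.

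The fits were tested on simulated data made from the real means, library sizes and dispersions. The data for the fit without the block held no replicate effect, and those for the block held one with the block's own dispersions. The fit without the block was thus not tested on data with a replicate effect, and the shares with and without it come from different data. For LPS against CON, 31.6% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 95.7% of those changed 4-fold were recovered without the block, with 13 false calls among 159 (11210 genes). With the block the shares were 78.3%, 92.9% and 100%, with 13 false calls among 194 (11223 genes). For SUR against LPS without the block, 41.8%, 83.3% and 91% were recovered, with 12 false calls among 156 (11215 genes). For SUR against CON without the block, 39.7%, 71.7% and 98.5% were recovered, with 9 false calls among 147 (11220 genes). With the block, false calls were 13 among 195 for SUR against LPS and 16 among 202 for SUR against CON. Coordinates are GRCm38 positions from the deposited table; of the 11281 tested genes, 11254 IDs were found in a RefSeq gene table, 10637 of these on a chromosome, and 9526 of those began at the same base. Results for some members of the gene lists are not reported here.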

Results

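RNA was sequenced from MH-S cells, a line of mouse alveolar macrophages, in 3 groups of 3 libraries: untreated (CON), LPS, and the group labelled suramin (SUR), whose protocol describes suramin together with LPS. Suramin is a polyanionic drug known to block purinergic receptors and the binding of several growth factors. Total counts ran from 15729402 (LPS 2) to 16675250 (SUR 3) over 14771 genes, of which 11281 were tested. The series sets out to relate suramin to pyroptosis, a lytic inflammatory cell death, in LPS-stimulated macrophages.

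The first principal component of log2 CPM held 52% of the variance and placed the LPS libraries (scores 39.7, 36 and 35.1) apart from CON (-9.9, -29.2 and -38.8) and SUR (-6.15, -14.7 and -12). The second held 27.4% and separated the libraries numbered 1 in every group (30.3, 24.2 and 29.3) from the rest (-8.5 to -20.6). The CON libraries also differed from each other in genes that LPS raised. The 175 genes taken were those called with a log2 fold change of at least 2 in LPS against CON. Their median log2 excess in CON 1 over CON 2 and CON 3 was 0.80 (interquartile range 0.48 to 1.60). It was -0.13 for LPS 1 and -0.14 for SUR 1 within their own groups. Tnf, chosen after its values were seen, stood at 404, 92.1 and 22.1 CPM in CON 1 to 3.

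**Figure D1:**
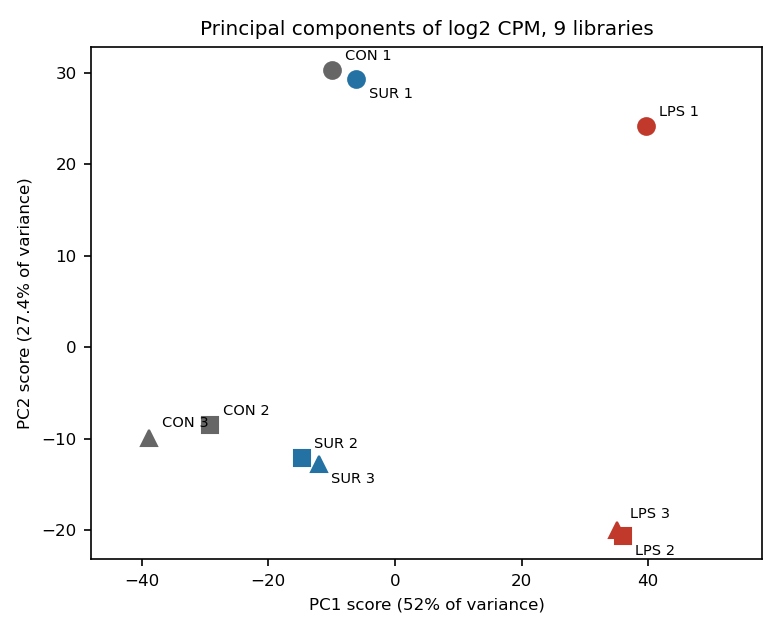
Scores of the 9 libraries on the first 2 principal components of log2 CPM, coloured by group and with a symbol per replicate number. PC1 (52% of the variance) sets the LPS libraries at 35.1 or above and all others at -6.15 or below, and PC2 (27.4%) sets the libraries numbered 1 at 24.2 or above and all others at -8.5 or below.

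The comparison of LPS with CON asked what LPS changed in these cells. LPS raised the mRNAs of inflammatory cytokines. Il1b and Il1a, the genes of the interleukin-1 cytokines, rose 95.9-fold and 99.5-fold (n = 3 libraries per group). Il1b went from 2.00 ± 2.31 CPM in CON to 194 ± 85.6 CPM in LPS, a log2 fold change of 6.58 (SE 0.778, adjusted p = 0.000534, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Il1a went from 0.587 ± 0.705 to 59.9 ± 30.5 CPM (log2 fold change 6.64, SE 0.767, adjusted p = 0.00047). These folds depended on CON 1. Within replicate numbers 1, 2 and 3 the log2 difference was 4.40, 7.19 and 10.5 for Il1b and 4.02, 8.01 and 7.99 for Il1a. Without the libraries numbered 1 the log2 fold changes were 8.39 and 8.70. Differences within numbers came from log2 CPM with a prior count of 2 added before the logarithm, which limits them at low counts. Il1b stood at 0.0595 CPM in CON 3, so its difference of 10.5 depends on that prior count. Of 95 calls under the naming rule, 24 had a fold more than 1.5 times larger without CON 1 and 0 one smaller by as much. Among genes that met the abundance rule for naming, the other largest rises were of Il6, an acute-phase cytokine (log2 fold change 4.91, SE 0.825), Acod1, the enzyme that makes itaconate (29.9-fold), the chemokine genes Ccl4 (29.2-fold), Cxcl3 (28.2-fold) and Cxcl10 (26.8-fold), and Traf1, an adaptor of TNF receptors (27.6-fold). Their adjusted p-values ran from 0.000241 for Traf1 to 0.0213 for Cxcl10. The call of Cxcl10 was lost without CON 2 (adjusted p = 0.0915) and without LPS 2 (0.0516).

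Of 26 tested cytokines and chemokines, 23 rose and 0 fell (26 rose adjusted over the list alone). The median log2 fold change of this list was 4.64, and camera gave an adjusted p of 6.85e-34. It was adjusted p = 0.0395 with an estimated correlation and 0.236 when the block was added. All 24 tested NF-kappaB targets and feedback genes rose (24 adjusted over the list alone), with a median of 2.46 and camera adjusted p = 4.19e-45 (adjusted p = 0.0395 with an estimated correlation, and 0.236 when the block was added). They included Traf1 and Ptgs2, the inducible cyclooxygenase, which rose from 16.5 ± 21.4 to 411 ± 103 CPM (log2 fold change 4.63, SE 0.868, adjusted p = 0.00566). Tnf rose by 3.60 on the log2 scale (SE 0.839, adjusted p = 0.0168) to 1932, 2002 and 2352 CPM, by 2.26, 4.44 and 6.72 within numbers 1, 2 and 3 and by 5.27 without the libraries numbered 1. Immediate-early and MAPK feedback genes moved likewise, with 24 of 31 higher and 1 lower (26 and 1 adjusted over the list alone) and a median of 1.84. Camera gave 1.06e-30 for this list, and adjusted p = 0.0216 with an estimated correlation, or 0.167 when the block was added. Examples were the MAPK phosphatase genes Dusp8 (log2 fold change 4.43) and Dusp1 (4.01) and the transcription factor gene Maff (3.73), whereas Dusp6, the gene of an ERK phosphatase, fell. Dusp1 showed the same order of the CON libraries as Tnf, from 32.1 CPM in CON 1 to 6.37 CPM in CON 3.

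Interferon-stimulated genes were mixed: 20 of 37 rose, 2 fell and 15 were not called (22 and 2 adjusted over the list alone). The median log2 fold change was 1.43, also with Ifi205, which had no count in any CON library, at its lower bound of 3 counts per library. Camera gave 9.34e-15, and adjusted p = 0.121 with an estimated correlation. Ifnb1, the interferon-beta gene, rose from 0.803 ± 1.09 to 25.4 ± 6.21 CPM (log2 fold change 4.96, SE 0.714, adjusted p = 0.00146). Ifit1, an antiviral RNA-binding protein gene, rose from 6.69 ± 7.69 to 136 ± 16.2 CPM (4.34, SE 0.656, adjusted p = 0.00189). Among TLR4 signalling components 10 rose and 4 fell of 27 (11 and 5 adjusted over the list alone), a split that became 6 and 5 with upper-quartile scaling or FPKM. Cd14, the LPS co-receptor, rose 7.68-fold and Irak2, a kinase of the same pathway, 3.93-fold. The camera adjusted p was 0.00846 for this list, and adjusted p = 0.121 with an estimated correlation. Coagulation and fibrinolysis genes held 6 rises and 1 fall among 15 (8 and 1 adjusted over the list alone, 9 and 2 with the replicate block). They included F3, which encodes tissue factor (11.3-fold). Camera gave 9.39e-05 there, and adjusted p = 0.0395 with an estimated correlation, or 0.236 when the block was added.

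The inflammasome and pyroptosis list bears on the question in the series title. Only mRNA was measured, so the list cannot show whether pyroptosis took place. That title names 3 of the list's genes, so its direction is not independent evidence. Of 28 tested members 7 rose, 2 fell and 19 were not called (8 and 2 adjusted over the list alone, 9 and 5 with the replicate block, and 12 and 7 with both). Nlrp3 (gene ID 216799; GRCm38 chromosome 11, 59541569 to 59566955), the inflammasome sensor, rose 11.6-fold from 81.5 ± 54.3 to 944 ± 82.7 CPM (log2 fold change 3.53, SE 0.412, adjusted p = 0.0005). Within replicate numbers 1, 2 and 3 its log2 difference was 2.57, 3.98 and 4.66. Il1rn, which encodes the interleukin-1 receptor antagonist, rose from 10.2 ± 0.572 to 45.9 ± 5.90 CPM (log2 fold change 2.17, adjusted p = 4.08e-05). The guanylate-binding protein genes Gbp2 and Gbp5, uncertain because of their close relatives, rose by 3.79 and 5.37 on the log2 scale. Txnip (chromosome 3, 96557957 to 96561862), which encodes a thioredoxin-binding protein, fell from 416 ± 68.5 to 117 ± 19.5 CPM, a 3.55-fold decrease (log2 fold change -1.83, SE 0.159, adjusted p = 0.00011).

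Casp1, Gsdmd and Il18 were not called between CON and LPS, with or without the replicate block. Casp1 (gene ID 12362; chromosome 9, 5298517 to 5307281), the inflammatory caspase, stood at 54.4 ± 5.49 CPM in CON and 59.0 ± 4.84 CPM in LPS (log2 fold change 0.12, SE 0.113, adjusted p = 0.589). Within numbers 1, 2 and 3 it was higher in LPS by 0.14, 0.08 and 0.14 on the log2 scale (adjusted p = 0.051 with the block). Gsdmd (gene ID 69146; chromosome 15, 75862144 to 75867408), the pore-forming gasdermin, stood at 54.7 ± 7.42 and 54.5 ± 7.76 CPM (-0.003, SE 0.150, adjusted p = 0.994). Il18 (gene ID 16173; chromosome 9, 50554700 to 50581841), a cytokine released through inflammasomes, was at 3.49 ± 0.846 and 3.91 ± 0.613 CPM (adjusted p = 0.718). Casp4, the caspase of the non-canonical inflammasome, was at 25.2 ± 3.68 and 31.9 ± 0.997 CPM (log2 fold change 0.34, adjusted p = 0.0551); it was called with the replicate block (adjusted p = 0.00552), by DESeq2 (0.0251) and limma-voom (0.0486), without CON 2, and without the libraries numbered 1 (0.0281). Pycard, the inflammasome adaptor, was at 19.1 ± 4.86 and 14.6 ± 2.08 CPM (log2 fold change -0.39, adjusted p = 0.397), and it was called with the block (adjusted p = 0.00757) and without the libraries numbered 1 (0.00288). Camera gave the whole list an adjusted p of 0.0129 toward higher values, which became 0.0623 with the replicate block, and adjusted p = 0.329 with an estimated correlation. Its median of 0.10 turned to -0.03 on FPKM. Ninj1, which encodes a protein of plasma membrane rupture, rose by 0.46 on the log2 scale (adjusted p = 0.0409). The Ninj1 call was lost without CON 1, CON 2, CON 3, LPS 2, LPS 3, SUR 2 or SUR 3 (adjusted p up to 0.137).

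**Figure D2:**
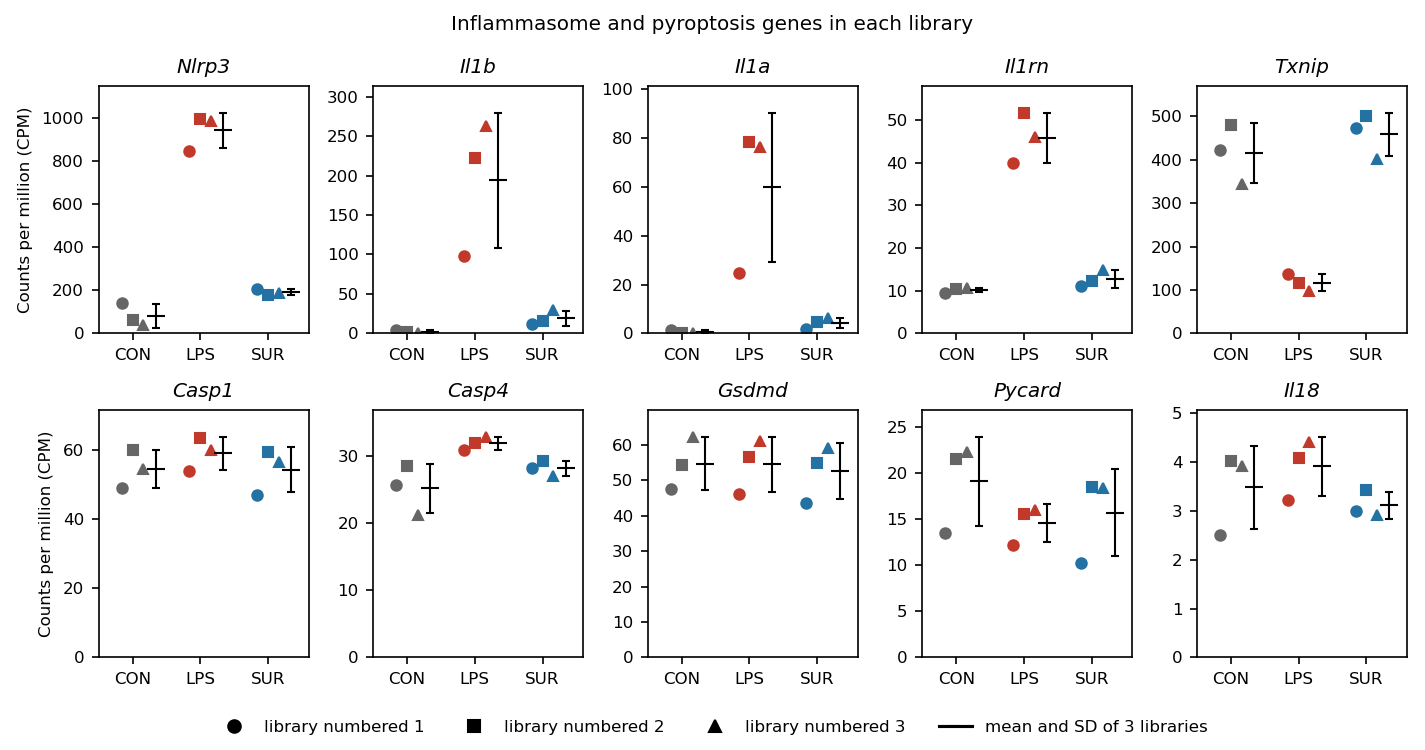
CPM (linear axis from 0) of 10 inflammasome and pyroptosis genes in each library of CON, LPS and SUR, with symbols for the replicate numbers and a bar for the mean and SD of 3 libraries. Nlrp3 averaged 81.5, 944 and 190 CPM and Txnip 416, 117 and 458 CPM in the 3 groups, while Gsdmd averaged 54.7, 54.5 and 52.5 CPM.

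Among genes that met the abundance rule, the largest falls with LPS were of Arrdc3, an arrestin-domain gene (5.03-fold lower), Gpr146, a G protein-coupled receptor gene (4.93-fold), Dusp6 (4.86-fold), the uncharacterised AI467606 (4.65-fold), Bmf, a pro-apoptotic BH3-only gene (4.11-fold), Ddit4, which encodes an inhibitor of mTOR signalling (4.08-fold), Klf10, a transcription factor gene (4.07-fold), and Inka1, the gene of a kinase inhibitor (3.92-fold). Their adjusted p-values lay between 4.16e-05 and 0.00149. Among apoptosis and p53 targets 10 rose and 3 fell of 23 (10 and 4 adjusted over the list alone, 10 and 6 with the block), with Fas, a death receptor gene (7.94-fold), and Bcl2l11, a BH3-only gene (5.00-fold), among the rises. Camera gave 1.14e-05, and adjusted p = 0.0905 with an estimated correlation. The list's median of 0.04 turned to -0.06 with upper-quartile scaling and with FPKM. Unfolded protein and integrated stress response genes held 7 rises and 1 fall among 22 (7 and 1 adjusted over the list alone, 12 and 5 with the block), including the stress transcription factor gene Atf3 (7.03-fold) and Ppp1r15a, which encodes a phosphatase subunit that reverses translational arrest (log2 fold change 3.46). Its camera adjusted p was 0.007, and adjusted p = 0.319 with an estimated correlation. Antigen presentation genes (5 rose and 1 fell of 14, 6 and 2 with the block), growth factors and receptors (4 and 0 of 16, 9 and 2 with the block) and endocytosis and scavenger receptors (4 and 1 of 19, 10 and 4 with the block) were also called by camera, at 0.0129, 0.0295 and 0.0295. Each of these calls was lost, at adjusted p = 0.292, 0.121 and 0.383 with an estimated correlation, and counts adjusted over the list alone were 5 and 1, 4 and 0, and 4 and 1. On FPKM the counts were 4 and 2, 2 and 0, and 4 and 1, and the antigen presentation median of 0.128 turned to -0.025. Clec4e, a C-type lectin receptor of macrophages, rose 6.97-fold and Cd83, a marker of activated antigen-presenting cells, 25.6-fold.

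The remaining lists were not called by camera. Sterol biosynthesis and uptake held 6 rises and 1 fall among 24 (7 and 2 adjusted over the list alone, 12 and 7 with the block, camera adjusted p = 0.0636), and upper-quartile scaling gave 4 and 4 and FPKM 4 and 5. LXR and lipid efflux genes held 1 rise and 3 falls among 10 (1 and 3 adjusted over the list alone, 2 and 3 with the block, camera 0.183), with Abcg1, a cholesterol exporter gene, 1.65-fold lower. Glycolysis and hypoxia genes held 4 rises and 1 fall among 26 (4 and 1 adjusted over the list alone, 10 and 3 with the block, camera 0.277). Heat shock genes held 3 rises among 12 (4 adjusted over the list alone, camera 0.0501, and 0.0316 with the block, which also called 6, or adjusted p = 0.335 with the block and an estimated correlation). NRF2 targets held 5 rises and 1 fall among 19 (5 and 1 adjusted over the list alone, 5 and 3 with the block, 3 and 4 on FPKM, camera 0.461), necroptosis and ferroptosis genes 3 rises among 16 (3, 0.365, 4 rises and 2 falls with the block), and alternative activation genes 2 among 13 (1, 0.277, 5 and 3 with the block, 1 rise and 1 fall with upper-quartile scaling or FPKM). Purinergic receptors and ectonucleotidases held 2 rises among 13 (2 adjusted over the list alone, camera 0.984, 3 rises and 3 falls with the block), with P2ry2, a nucleotide receptor gene, 1.93-fold higher. Of 19 alveolar macrophage genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera 0.803, 3 and 5 with the block). Lysosome genes held 1 fall among 35 (0 adjusted over the list alone, camera 0.803, 4 rises and 5 falls with the block) and cell cycle genes 1 fall among 32 (0, 0.62, 4 and 9 with the block). Lysosome falls were 2 with upper-quartile scaling and 5 on FPKM, and cell cycle falls 4 with either, with 0 rises. Purinergic, alveolar macrophage, NRF2, necroptosis and LXR genes had medians, means and camera directions that differed in sign. In edgeR's test 0 of 28 nuclear genes of oxidative phosphorylation and 0 of 12 housekeeping genes were called (0 adjusted over either list alone, 5 and 0, and 4 rises and 2 falls, with the block). On FPKM 1 of each fell. Markers of other cell types were nearly unmeasured: 0 of 2 epithelial and 0 of 7 lymphocyte and neutrophil markers in the table, and 2 of 7 fibroblast and endothelial ones, had counts enough to test. edgeR called 0 of the latter (0 at unadjusted p < 0.05, by DESeq2 and by limma-voom, 1 with the block).

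Between CON and LPS, 1013 genes rose and 1056 fell, 18.3% of the 11281 tested, and 387 and 244 of these changed at least 2-fold. With the replicate block 2269 rose and 2445 fell, and all 2069 genes called without it kept their call and sign. Leaving out CON 3 lowered the total to 1379. Upper-quartile scaling gave 765 rises and 1709 falls, and the authors' FPKM scaling, in which the median gene sat 0.131 lower on the log2 scale than with TMM, gave 662 and 2000. Cytokine, NF-kappaB, interferon, immediate-early and coagulation lists kept their direction under both.

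The comparison of SUR with LPS asked what differed when suramin was present, on the reading that SUR cells also received LPS. On that reading no group received suramin alone, so opposition to LPS cannot be parted from suramin's own effect on a gene. Among genes that met the abundance rule, most of the largest falls were of interferon-stimulated and chemokine genes. Ifit1 fell 44.5-fold, from 136 ± 16.2 CPM in LPS to 3.05 ± 0.687 CPM in SUR (log2 fold change -5.48, SE 0.714, adjusted p = 0.00126, n = 3 per group). Ccl4 fell 20.3-fold, from 896 ± 81.4 to 44.0 ± 5.44 CPM (-4.35, SE 0.739, adjusted p = 0.00437). The other largest falls under that rule were of Cxcl10 (18.1-fold), Rsad2, which encodes the antiviral enzyme viperin (18.1-fold), the T cell-attracting chemokine gene Ccl5 (17.6-fold), the ubiquitin-like modifier gene Isg15 (16.5-fold), Il6 (log2 fold change -3.90, SE 0.772) and Il1a (14.1-fold). Their adjusted p-values ran from 0.000344 for Ccl5 to 0.0343 for Cxcl10. The Cxcl10 call was lost without CON 2 or any single LPS or SUR library (adjusted p up to 0.127, without SUR 2). The spread of Cxcl10 among CON 1 to 3 (124, 26.4 and 0.536 CPM) also enters this test through the shared dispersion. The authors' DESeq2 q-value for the same fall was 1.19e-124.

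Of 37 interferon-stimulated genes 20 fell, 1 rose and 16 were not called (22 and 2 adjusted over the list alone, 23 and 3 with the block), with a median log2 fold change of -0.90 and camera adjusted p = 1.09e-16, or adjusted p = 0.202 with an estimated correlation. Ifnb1 fell from 25.4 ± 6.21 to 0.330 ± 0.185 CPM (75.2-fold, adjusted p = 0.00121), while Oas2, an antiviral sensor gene chosen after its values were seen, rose by 0.49 on the log2 scale (adjusted p = 0.012). Cytokines and chemokines held 19 falls and 0 rises among 26 (20 and 0 adjusted over the list alone), with a median of -2.99 and camera 3.17e-22 (adjusted p = 0.202 with an estimated correlation). Tnf, read after its values were seen, was among the 7 not called. Its SUR libraries stood at 1326, 1159 and 1597 CPM against 1932, 2002 and 2352 CPM in LPS. The log2 fold change was -0.62 (SE 0.758, adjusted p = 0.663, 0.411 with the block and 0.207 without the libraries numbered 1). Within numbers 1, 2 and 3 the log2 difference of Tnf was -0.54, -0.79 and -0.56. The spread of Tnf among the CON libraries also enters this SE and p-value. NF-kappaB targets held 18 falls and 0 rises among 24 (20 and 0 adjusted over the list alone), including Traf1 (9.71-fold lower), the NF-kappaB subunit gene Rel (3.49-fold) and its inhibitor Nfkbie (3.37-fold). Camera gave 1.05e-23, and adjusted p = 0.202 with an estimated correlation. Ptgs2, read after its values were seen, averaged 89.2 ± 23.6 CPM in SUR against 411 ± 103 CPM in LPS (adjusted p = 0.0852). It was called with the block (0.000865) and without the libraries numbered 1 (1.09e-05).

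Immediate-early and MAPK feedback genes were divided, with 14 lower and 4 higher of 31 (15 and 4 adjusted over the list alone, median -0.37, camera 7.56e-06, and adjusted p = 0.241 with an estimated correlation). Dusp8 fell 13.9-fold, Atf3 6.54-fold and Dusp16, another MAPK phosphatase gene, 5.07-fold. Egr1, a serum-response transcription factor gene named after its values were seen, rose 1.95-fold (adjusted p = 0.0176). Fos, the AP-1 subunit gene, named after its values were seen, rose 2.48-fold to 70.4 ± 8.11 CPM (adjusted p = 0.000294). TLR4 signalling components held 9 falls and 5 rises among 27 (10 and 6 adjusted over the list alone, 15 and 7 with the block, camera 0.0611, 0.0311 with the block, and adjusted p = 0.403 with the block and an estimated correlation); upper-quartile scaling gave 7 and 6 and FPKM 5 and 6. Cd14 fell 3.45-fold, Irak2 2.79-fold and Ticam1, the adaptor gene of the interferon arm, 2.13-fold, whereas Map3k8, a kinase upstream of ERK, rose 2.59-fold. Coagulation and fibrinolysis genes held 7 falls and 1 rise among 15 (8 and 1 adjusted over the list alone, 9 and 2 with the block), with F3 8.56-fold lower. Thbd, which encodes thrombomodulin and was chosen after its values were seen, was their riser (5.04-fold). The list's median was -0.65, also with Serpinb2, which had no count in SUR, at its bound of 3 counts per library, and camera gave 4.19e-05 (adjusted p = 0.119 with an estimated correlation).

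In the inflammasome and pyroptosis list 6 of 28 fell, 1 rose and 21 were not called (7 and 1 adjusted over the list alone, 8 and 4 with the block). The list was not called by camera (adjusted p = 0.0516, 0.226 with the block, 0.423 with an estimated correlation), and its median of -0.06 turned to 0.03 with upper-quartile scaling and 0.05 on FPKM. Nlrp3 fell 4.96-fold, to 190 ± 14 CPM (log2 fold change -2.31, SE 0.391, adjusted p = 0.00429), by 2.05, 2.49 and 2.38 on the log2 scale within numbers 1, 2 and 3. Il1b (gene ID 16176; chromosome 2, 129364569 to 129371164) fell to 19.4 ± 9.51 CPM (log2 fold change -3.32, SE 0.618, adjusted p = 0.00654). Il1a (gene ID 16175; chromosome 2, 129299609 to 129310186) to 4.24 ± 2.14 CPM (-3.82, SE 0.603, adjusted p = 0.00307). Il1rn fell 3.59-fold, and Gbp2 and Gbp5 fell, with the same reservation as before, with log2 fold changes of -2.90 and -6.90. Txnip rose 3.91-fold, to 458 ± 50.3 CPM (adjusted p = 0.000211).

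Gsdmd, Il18, Casp1, Casp4 and Pycard were not called between SUR and LPS without the block. Gsdmd stood at 52.5 ± 7.99 CPM in SUR (log2 fold change -0.05, SE 0.150, adjusted p = 0.87) and Il18 at 3.12 ± 0.273 CPM (-0.33, SE 0.217, adjusted p = 0.369). Casp1 was at 54.3 ± 6.63 CPM (-0.12, SE 0.112, adjusted p = 0.549), a difference that the block called (adjusted p = 0.0428). Casp4 was at 28.1 ± 1.13 CPM (-0.18, adjusted p = 0.298) and Pycard had a log2 fold change of 0.11 (SE 0.262, adjusted p = 0.846). Ninj1 was at 114 ± 13.3 CPM (-0.41, adjusted p = 0.0638), called with the block (0.000102), by DESeq2 (0.025), without LPS 1 (0.0157) and without the libraries numbered 1.

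Under the same rule, the largest rises in SUR over LPS were of genes that LPS had lowered: Bmf (4.96-fold), Arrdc3 (4.53-fold), Klf10 (4.21-fold), Txnip, Gpr146 (3.78-fold), AI467606 (3.75-fold), Sema4c, a semaphorin gene (3.43-fold), and Dusp6 (3.30-fold), with adjusted p-values from 0.000211 to 0.00319. Glycolysis and hypoxia genes held 12 falls and 0 rises among 26 (13 and 0 adjusted over the list alone, 21 and 2 with the block, 8 and 0 with upper-quartile scaling, 7 and 1 on FPKM), with a median of -0.27 and camera 2.94e-05 (adjusted p = 0.376 with an estimated correlation). The glucose transporter gene Slc2a1 fell 2.24-fold, the lactate transporter gene Slc16a3 1.86-fold and the collagen prolyl hydroxylase gene P4ha1 1.86-fold. Acod1 fell by 3.74 on the log2 scale (adjusted p = 0.0131), a call lost without SUR 2 (0.0637) or SUR 3. Apoptosis and p53 targets held 9 falls and 4 rises among 23 (10 and 5 adjusted over the list alone, 11 and 7 with the block, camera 0.0435, 0.297 with the block and adjusted p = 0.387 with an estimated correlation, the median of -0.10 turned to 0.03 on FPKM). Fas fell 3.58-fold and Bcl2l11 3.22-fold, whereas Sesn1, a stress-induced inhibitor of mTOR signalling, rose 2.66-fold and Trp53inp1, a p53-induced gene, 2.27-fold.

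Stress and presentation lists were lower by camera, each lost with an estimated correlation. Unfolded protein and integrated stress response genes held 4 falls and 1 rise among 22 (5 and 1 adjusted over the list alone, 14 and 5 with the block, camera 0.029, adjusted p = 0.412 with an estimated correlation), with the chaperone gene Hspa5 1.42-fold lower and Ddit3, the gene of the transcription factor CHOP, 1.57-fold higher. The median of -0.14 was 0.001 on FPKM. Heat shock genes held 3 falls among 12 (3 adjusted over the list alone, 8 with the block, 1 with upper-quartile scaling or FPKM, camera 0.029, adjusted p = 0.376 with an estimated correlation). Antigen presentation genes held 4 falls and 1 rise among 14 (4 and 1 adjusted over the list alone, 7 and 2 with the block, camera 0.0374, adjusted p = 0.376 with an estimated correlation), with Cd83 5.72-fold lower and Tap1, a peptide transporter gene, 1.37-fold higher. The median of -0.13 was 0.02 on FPKM. Nuclear genes of oxidative phosphorylation held 1 fall among 28 (0 adjusted over the list alone, 7 at unadjusted p < 0.05, 15 with the block, 3 by DESeq2 and 0 by limma-voom, camera 0.0432, adjusted p = 0.626 with an estimated correlation), and the median of -0.13 was 0.02 on FPKM, where 1 rose and 0 fell.

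The remaining lists were not called by camera between SUR and LPS. Sterol biosynthesis held 6 falls among 24 (6 adjusted over the list alone, 10 and 5 rises with the block, camera 0.0534, 0.0382 with the block, and adjusted p = 0.451 with the block and an estimated correlation), and its median of -0.12 was 0.01 on FPKM. LXR genes held 3 rises and 1 fall among 10 (3 and 1 adjusted over the list alone, 3 and 3 with the block, camera 0.19), Abcg1 being 1.65-fold higher. Endocytosis and scavenger receptors held 1 rise and 4 falls among 19 (1 and 4 adjusted over the list alone, 4 and 9 with the block, camera 0.139, median -0.12, and 0.05 on FPKM), with Clec4e 3.03-fold lower. NRF2 targets held 1 and 3 among 19 (1 and 3 adjusted over the list alone, 1 and 7 with the block, camera 0.19), with the cystine transporter gene Slc7a11 3.37-fold lower. Necroptosis and ferroptosis genes held 1 and 2 of 16 (1 and 2 adjusted over the list alone, 1 and 7 with the block, camera 0.317), growth factors and receptors 1 and 2 of 16 (1 and 2, 3 and 8, 0.478), alveolar macrophage genes 1 and 2 of 19 (1 and 2, 6 and 6, 0.478), lysosome genes 1 and 1 of 35 (1 and 0, 5 and 12, 0.558), housekeeping genes 1 and 0 of 12 (0 and 0, 2 and 6, 0.615), and purinergic receptors 0 and 1 of 13 (0 and 1, 1 and 3, 0.834), with P2ry2 1.91-fold lower. In edgeR's test 0 of 13 alternative activation genes (0 adjusted over the list alone, 2 at unadjusted p < 0.05, 1 by DESeq2, 0 by limma-voom, 7 with the block, camera 0.709) and 0 of 32 cell cycle genes (0, 4, 2, 0, 11, 0.834) were called, and 0 of the 2 fibroblast and endothelial markers. On FPKM the rises and falls were 2 and 2 for NRF2 targets, 2 and 1 for growth factors, 2 and 0 for lysosome genes, 1 and 0 for alternative activation and 3 and 0 for cell cycle genes. LXR, purinergic and cell cycle genes had medians, means and camera directions that differed in sign.

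Between LPS and SUR, 1048 genes rose and 895 fell (240 and 251 at least 2-fold), and 2547 and 2562 with the replicate block, which kept all 1943 calls. The total was 1208 without SUR 2 and 1255 without SUR 3. Upper-quartile scaling gave 1595 rises and 616 falls, and FPKM, with its median gene 0.132 higher on the log2 scale, 1911 and 506.

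A gene was counted as moved back if it was called in LPS against CON and in the opposite direction in SUR against LPS. Of the 1013 genes that LPS raised, 714 (70.5%) were lower in SUR, with Ifit1, Ccl4, Cxcl10, Rsad2, Ccl5, Isg15, Il6 and Il1a moving the most among genes with a mean log2 CPM of at least 4 and no overlap between the groups' libraries. Of the 1056 that LPS lowered, 790 (74.8%) were higher in SUR, led under the same rule by Bmf, Arrdc3, Klf10, Txnip, Gpr146, AI467606, Sema4c and Dusp6. Only 1 raised gene was higher again and 0 lowered genes were lower again by edgeR's test (19 and 5 with the block). Independent lists of the same sizes would share 80.4 and 98.1 genes. Because the LPS libraries enter both comparisons, data were simulated with the LPS effect kept and SUR equal to LPS: in 50 runs the median count of raised then lower genes was 0 and the highest 1. The correlation of the log2 fold changes across genes was -0.888 (-0.181 in that simulation), and the covariance -0.282 (-0.0278 simulated). The total of 1504 was 3610 with the block and 1025 without LPS 2. The split of 714 and 790 depended on scaling: it was 529 and 1255 with upper-quartile scaling and 452 and 1474 on FPKM. The highest simulated count of lowered then higher genes was also 1. With no SUR effect simulated, few genes could be called in SUR against LPS, so low counts were fixed in advance. They do not show how many moved-back genes the shared libraries would add to a SUR effect unrelated to LPS. The covariance does not rest on calls. Its simulated value of -0.0278, against -0.282, argues against shared noise as the main source of the opposition across genes. The simulation drew each gene separately. With 3 LPS libraries the comparisons could not be given separate LPS libraries in equal numbers, so part of the excess may still come from the shared libraries.

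**Figure D3:**
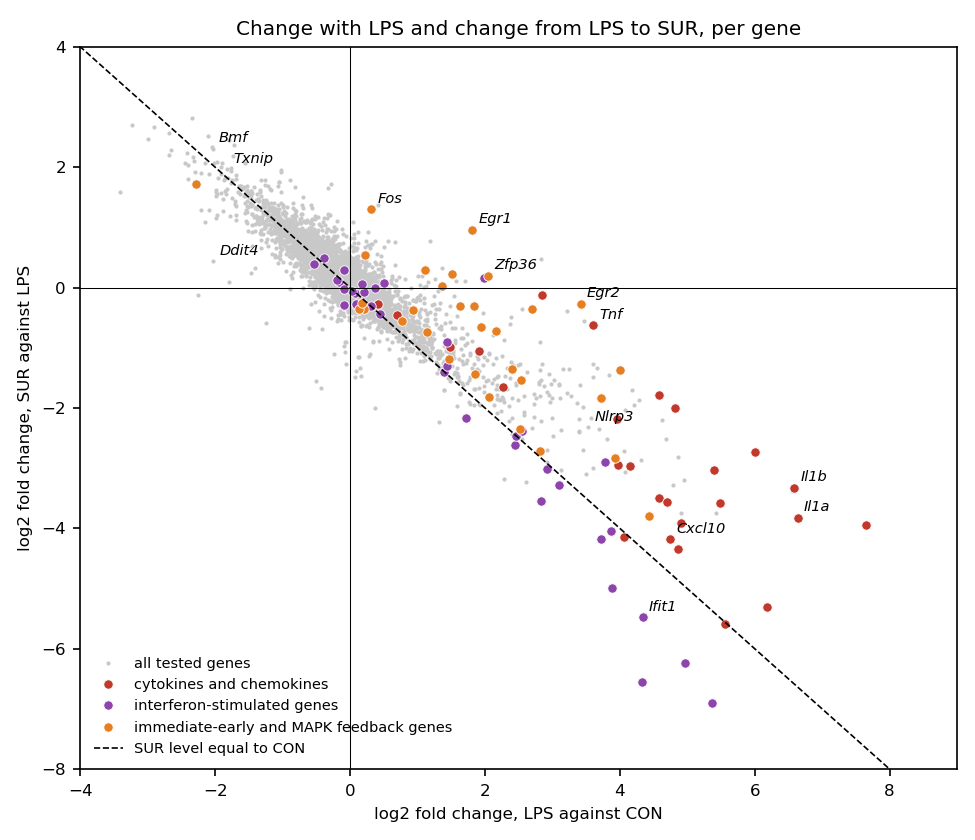
Log2 fold change of LPS against CON (x) and of SUR against LPS (y) for 11278 tested genes, with cytokine, interferon-stimulated and immediate-early genes coloured and a dashed line where SUR equals CON. The correlation across genes was -0.888, and 1504 genes moved back.

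SUR against CON asked how far SUR cells, on the reading that they also received LPS, differed from untreated cells. Of the 48 genes called, 12 were immediate-early and MAPK feedback genes, all higher in SUR. Egr1 rose 6.83-fold over CON, to 85.1 ± 19.8 CPM (log2 fold change 2.77, SE 0.242, adjusted p = 0.00493, n = 3 per group). Egr2, a related transcription factor gene, rose 8.89-fold to 63.7 ± 17.9 CPM (3.15, SE 0.332, adjusted p = 0.0117), and Fos, chosen after its values were seen, 3.07-fold (adjusted p = 0.00477). Socs3, a feedback inhibitor of cytokine signalling (7.57-fold), the ERK phosphatase gene Dusp2 (5.08-fold), Zfp36, whose product destabilises cytokine mRNAs (4.72-fold), the transcription factor gene Irf1 (4.39-fold), Tagap, a GTPase-activating protein gene (3.88-fold), and Nfkbid, an atypical inhibitor of NF-kappaB (3.70-fold), were the other largest rises under the abundance rule, with adjusted p-values from 0.0195 to 0.0495. The only falls passing the rule were of Ddit4 (3.01-fold lower), the lysophosphatidic acid receptor gene Lpar6 (2.33-fold lower, to 12.3 ± 0.428 CPM) and the lymphotoxin receptor gene Ltbr (1.24-fold lower). The remaining fall, of Id1, an inhibitor of DNA binding, from 3.48 to 0.662 CPM, was read after its values were seen.

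Of 31 immediate-early and MAPK feedback genes 12 rose and 0 fell (20 and 0 adjusted over the list alone, 22 and 1 with the block, 17 by DESeq2), with a median of 1.05 and camera 9.92e-62 (adjusted p = 0.00264 with an estimated correlation, and 0.0757 when the block was added). Among 26 cytokines and chemokines edgeR called 0, against 16 at unadjusted p < 0.05, 16 adjusted over the list alone, 6 by DESeq2, 0 by limma-voom, 17 with the block and 20 without the libraries numbered 1. As a set they were higher (camera 7.93e-23, adjusted p = 0.101 with an estimated correlation). Tnf, read after its values were seen, had a log2 fold change of 2.98 (SE 0.816, adjusted p = 0.226) and was called with the block (0.011) and without the libraries numbered 1 (5.42e-05). NF-kappaB targets held 1 rise among 24 (18 adjusted over the list alone, 18 with the block, 13 by DESeq2 and 2 by limma-voom), that of Sod2, the mitochondrial superoxide dismutase gene (1.97-fold). The median was 0.95 and camera 1.44e-35 (adjusted p = 0.0685 with an estimated correlation). Interferon-stimulated genes held 1 rise among 37, Irf1 (1 and 1 adjusted over the list alone, 3 and 1 with the block), with a median of -0.06, a mean of -0.02 and a camera test toward higher values (adjusted p = 0.894). Apoptosis and p53 targets held 2 rises among 23, of Bcl2l11 (1.55-fold) and the survival gene Mcl1 (1.51-fold, 8 adjusted over the list alone, 12 and 1 with the block, camera 3.18e-09, adjusted p = 0.0541 with an estimated correlation). TLR4 components held 1 rise, Map3k8 (3.44-fold, 3 adjusted over the list alone, 6 with the block, camera 0.0358, 0.0564 with the block and adjusted p = 0.208 with an estimated correlation), and growth factors 1, Gdf15, a stress-induced cytokine gene (2.30-fold, 3 adjusted over the list alone, 5 with the block, camera 0.000592, adjusted p = 0.0541 with an estimated correlation). Glycolysis and hypoxia genes held 1 fall among 26, Ddit4 (10 adjusted over the list alone, 17 with the block, median -0.18, camera 5.26e-09, adjusted p = 0.208 with an estimated correlation).

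In the inflammasome and pyroptosis list edgeR called 0 of 28 between SUR and CON (0 adjusted over the list alone, 5 at unadjusted p < 0.05, 0 by DESeq2 and by limma-voom, 4 with the block, 4 without the libraries numbered 1, camera 0.0616). Nlrp3 had a log2 fold change of 1.22 (SE 0.381, adjusted p = 0.301), Il1b one of 3.26 (SE 0.762, adjusted p = 0.142) and Il1a one of 2.82 (adjusted p = 0.274). With the block these were called (adjusted p = 0.0174, 0.00562 and 0.0159), as they were without the libraries numbered 1 (1.33e-05, 6.76e-05 and 3.47e-06). Without CON 1 alone Nlrp3 (0.00231) and Il1b (0.0458) were called. Casp1 (-0.002, adjusted p = 1), Gsdmd (-0.06, 0.995), Casp4 (0.16, 0.778), Pycard (-0.28, 0.892), Il18 (-0.16, 0.967) and Txnip (0.14, 0.933) were not called. Nuclear genes of oxidative phosphorylation were lower as a set (camera 0.00221, adjusted p = 0.664 with an estimated correlation) with 0 of 28 called (0 adjusted over the list alone, 4 at unadjusted p < 0.05, 0 by DESeq2 and by limma-voom, 5 with the block). Alternative activation genes held 1 rise among 13, Egr2 (1 adjusted over the list alone, camera 0.0782).

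edgeR called 0 members of the remaining lists between SUR and CON, as did limma-voom. For these, the counts at unadjusted p < 0.05, adjusted over the list alone, by DESeq2 and with the block, and the camera adjusted p, were 2, 0, 0, 6 and 0.0782 for lysosome genes, 4, 1, 1, 3 and 0.0794 for endocytosis and scavenger receptors, 6, 1, 2, 5 and 0.14 for the stress response, and 2, 1, 1, 3 and 0.222 for antigen presentation. They were 3, 0, 2, 6 and 0.416 for alveolar macrophage genes, 0, 0, 0, 2 and 0.484 for NRF2 targets, 0, 0, 0, 2 and 0.524 for the cell cycle, 1, 0, 0, 3 and 0.571 for coagulation, 2, 0, 0, 3 and 0.787 for LXR genes, and 0, 0, 0, 0 and 0.798 for purinergic receptors. For sterol biosynthesis they were 4, 0, 1, 7 and 0.929, for heat shock genes 2, 2, 2, 3 and 0.971, for necroptosis and ferroptosis 0, 0, 0, 4 and 0.971, and for housekeeping genes 1, 1, 1, 1 and 0.971. Of the 2 tested fibroblast and endothelial markers 0 were called by any of these. Medians, means and camera directions differed in sign for sterol, heat shock, necroptosis and housekeeping genes.

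In total 48 genes were called, 44 higher and 4 lower, against 1041 at unadjusted p < 0.05, 259 by DESeq2 and 49 by limma-voom, and 831 and 471 with the replicate block. The total was 0 without CON 2, 4 without CON 3, 5 without SUR 3 and 168 without CON 1, and 0 of the 16 named calls held in every such fit: Egr1 and Lpar6 were lost only without CON 2 (both 0.0668), Egr2 also without CON 3.

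**Figure D4:**
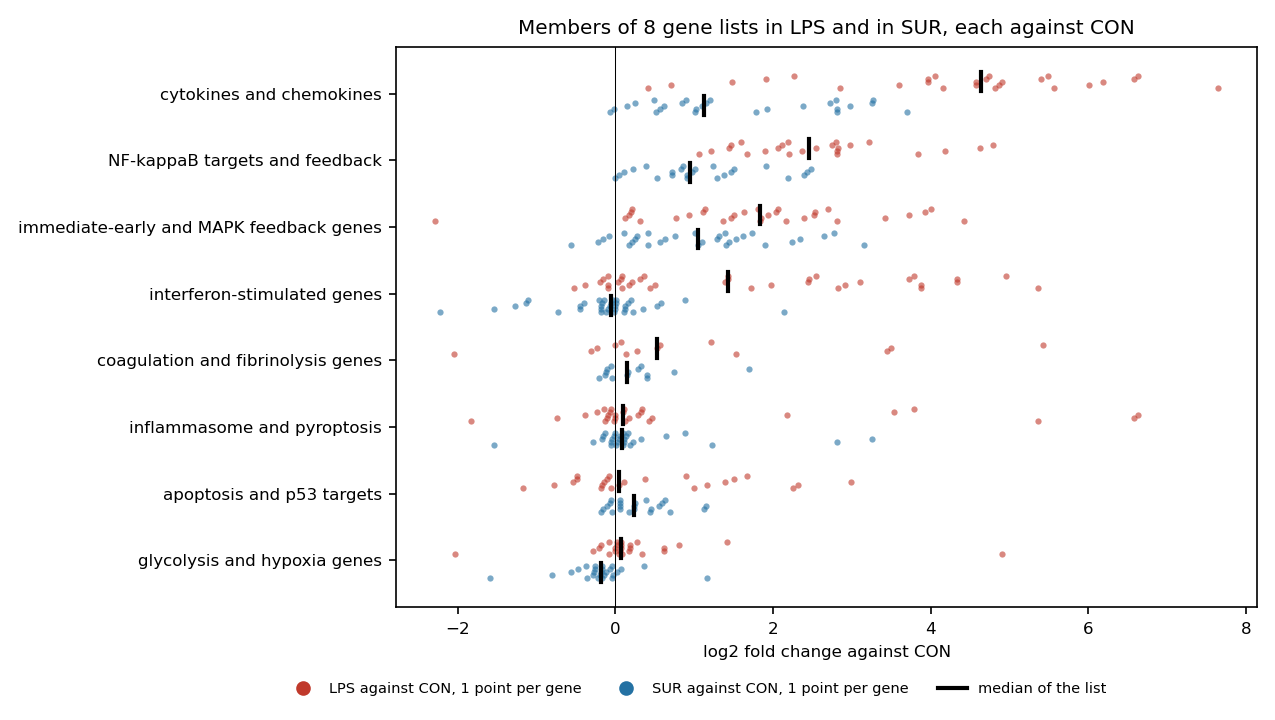
Log2 fold changes against CON of the members of 8 gene lists in LPS and in SUR, with a bar at each list's median. The median of interferon-stimulated genes was 1.43 in LPS and -0.06 in SUR, and that of immediate-early genes 1.84 and 1.05.

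The authors' deposited DESeq2 comparison reached q < 0.05 for 1837 genes in LPS against CON (1001 higher, 836 lower), 1916 in SUR against LPS (962 and 954) and 172 in SUR against CON (158 and 14). Of these, 1753, 1737 and 48 were also called here, and the log2 fold changes correlated at 0.9998, 0.9997 and 0.9987. The authors' log2 fold changes for Nlrp3 were 3.54 in LPS against CON (q = 7.84e-09) and -2.31 in SUR against LPS (q = 1.63e-100), and those for Gsdmd and Casp1 in LPS against CON were 0.008 (q = 0.991) and 0.13 (q = 0.792).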

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

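The fits without the libraries numbered 1 and the replicate block without CON 1 were chosen only after the result was seen. The counts of called genes were 2069 for LPS against CON, 1943 for SUR against LPS, 48 for SUR against CON and 1504 moved back, with 9, 7 and 0 called members of the inflammasome and pyroptosis list. The replicate block raised these to 4714, 5109, 1302 and 3610, with 14, 12 and 4 members and lost or reversed no call of a gene. The block without CON 1 gave 4585, 5553, 1390 and 3649, with 14, 13 and 6 members. Without the libraries numbered 1 the counts were 3415, 3391, 587 and 2509, with 4 members between SUR and CON. A threshold of 0.01 left 1172, 979, 3 and 805 genes, and a test against a 1.5-fold change left 541, 333, 4 and 302. For SUR against CON alone, DESeq2 gave 259, limma on log2(FPKM + 1) without a filter 27, and only the 6 libraries compared 4. Leaving out 1 library gave as few as 1379 (without CON 3), 1208 (without SUR 2), 0 (without CON 2) and 1025 (without LPS 2). Without CON 2 the list between SUR and CON also had 0 members. Of 25 gene lists, 12, 11 and 8 were called with a preset correlation and 4, 0 and 1 with an estimated correlation. With the block the lists called were 12, 12 and 7, and 0, 0 and 0 with an estimated correlation. The block lost the list calls of inflammasome and pyroptosis genes in LPS against CON (adjusted p = 0.0623), apoptosis in SUR against LPS (0.297) and TLR4 components in SUR against CON (0.0564). Whether more genes rose or fell changed with the setting, in these cases among others. LPS against CON had 1013 rises and 1056 falls, but 1053 and 1024 with relative log expression, 996 and 866 without a filter and 1215 and 1123 by DESeq2. SUR against LPS had 1048 and 895, but 874 and 886 without a filter and 140 and 193 in the test against a 1.5-fold change. Genes moved back were 714 raised and 790 lowered by LPS, but 878 and 866 by DESeq2, 529 and 1255 with upper-quartile scaling and 452 and 1474 on log2(FPKM + 1).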

Other observations

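The tests of carry-over with its highest share, of a batch with its expected shift and of sequencing depth, the comparison of removed shares between lists, and all KEGG pathway tests were chosen only after the result was seen; the tests of GC content and length, of CON 1 and of low counts, and all regroupings were written before their values were read. By camera, 9 of 25 gene lists differed between the libraries numbered 1 and the others, tested over the groups together, and 2 of them, of cell cycle and alveolar macrophage genes, also with an estimated correlation. With the groups held fixed, 3053 genes were higher and 2910 lower in libraries 1 than in libraries 2 and 3, against 6 and 3 genes between libraries 2 and 3. Of 32 cell cycle genes 28 were higher and 0 lower (median log2 difference 1.09, camera adjusted p = 1.78e-60, 0.00365 with an estimated correlation). Among them were Ube2c, a ubiquitin-conjugating enzyme gene of mitosis (2.12), and the kinetochore gene Cenpf (1.94). Ctsk, which encodes the protease cathepsin K (-3.35), and Tgfbi, a matrix protein gene (-2.42), were the furthest below among genes with a mean log2 CPM of at least 4. Of 19 alveolar macrophage genes 3 were higher and 10 lower (camera 1.64e-07, 0.0436 with an estimated correlation). The other lists were endocytosis and scavenger receptors (4 higher, 12 lower, camera 4.48e-05, and 0.065 with an estimated correlation), lysosome genes (4 and 24, 0.00133, 0.321), sterol biosynthesis (1 and 15, 0.00179, 0.322), glycolysis and hypoxia (11 and 1, 0.00184, 0.322), purinergic receptors (0 and 9, 0.00222, 0.139), interferon-stimulated genes (17 and 1, 0.00856, 0.496) and NRF2 targets (3 and 13, 0.0215, 0.321).

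Of 304 KEGG pathways camera called 78 higher in LPS than in CON, 77 lower in SUR than in LPS, and 68 higher and 17 lower in SUR than in CON, but 0 in any comparison with an estimated correlation. TNF signaling had the smallest adjusted p between SUR and CON (higher, 2.11e-17). The 17 included Ribosome (129 genes, median log2 fold change -0.10, camera adjusted p = 6.95e-09), Oxidative phosphorylation (105 genes, -0.10, 5.31e-06) and Proteasome (44 genes, -0.08, 0.000742). edgeR called 0 members of these 3, and with an estimated correlation the adjusted p-values were 0.405, 0.59 and 0.529. Ribosome biogenesis held 12 falls and 1 rise among 71 genes in SUR against LPS (camera 0.000573, 0.749 with an estimated correlation) and 8 rises in LPS against CON (0.0155, and 0.815).

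Genes that LPS raised also differed between the untreated libraries, with CON 1 the highest. Carry-over of LPS material would give CON 1 the same share of the LPS level for every gene. With LPS 1 as the source, the shares ran from 4.58% for Il1b to 20% for Tnf over 20 strongly raised genes, picked for a low level in CON 3. With LPS 2 and LPS 3 as the source the lowest shares were 1.56% and 1.6%, both of Il1a. The ratio of the 90th to the 10th percentile of the shares was at least 2.63, against an upper limit of 1.27 in simulated carry-over. That limit holds counting noise and not differences between separate cultures, so carry-over stays open. Its share cannot exceed the whole level of any gene in CON 1, here that of Il1b with a 95% allowance for counting error: 5.78% with LPS 1 as the source, 2.55% with LPS 2 and 2.17% with LPS 3. Taking these off left a median log2 excess of 0.31 (interquartile range -0.24 to 0.75), 0.55 (0.05 to 1.26) and 0.59 (0.11 to 1.27), while CON 2 exceeded CON 3 by a median of 0.40 with nothing taken off. The batch that sets libraries 1 apart also stays open: the larger median excess in LPS 1 or SUR 1 was -0.13, but the amount added in CON 1 would shift the median in LPS 1 by only 0.11 and in SUR 1 by 0.35, where suramin could itself hold it down. No biological explanation was tested.

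The separation of the libraries numbered 1 could come from GC content and transcript length or from sequencing depth. After GC content and transcript length were regressed out (97.9% of genes had values, and 3.53% of the variance was explained), the cell cycle median was still 1.06 (interquartile range 0.34 to 1.44). The mean total of libraries 1 was 1.02 times that of the others. Both results argue against a technical origin of these kinds, and no test here parts culture density, passage or day. The 10 most abundant genes of each library held 6.41%, 6% and 6.22% of the counts in CON 1, LPS 1 and SUR 1. In the other libraries they held 7.07% to 7.59%, and the origin of this difference was not tested.

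The median shares of the LPS rise that SUR removed were compared between interferon-stimulated and immediate-early genes. Over genes that LPS raised at least 2-fold, SUR removed a median of 105% of the log2 rise in 20 interferon-stimulated genes (interquartile range 93% to 126%). In 22 immediate-early genes the median was 41.5% (13.9% to 76%), a difference of 63.6 percentage points, and over all 387 such genes it was 72.2%. No group received suramin alone, so a removed share cannot be parted from suramin's own effect on a gene. Whether this exceeds chance cannot be told, since genes of a list move together and the difference was seen first: with an estimated correlation the lists had adjusted p = 0.202 and 0.241 in SUR against LPS. Without CON 1 the medians were 86.7% in the interferon-stimulated genes and 37.5% in the immediate-early genes. The median of 105% thus depended on CON 1 and does not show that the whole rise was removed. The difference between the lists was 49.2 points without CON 1, which argues against the raised control as its whole cause. It was 57.4 over genes of at least 10 CPM in SUR, but that minimum is set on the SUR level, which the removal itself lowers, and kept 5 and 18 genes, so low counts stay open. What gives rise to the difference was not tested.

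The 6 libraries of a comparison can be regrouped in only 10 ways, too few for a share under 0.05. For called genes 1 of 10 groupings, the real one, reached the real count in LPS against CON (2069, highest other 0), SUR against LPS (1943, 0), SUR against CON (48, 0) and genes moved back (1504, 0). For pyroptosis list members it was 1 of 10 in LPS against CON (9, highest other 0) and in SUR against LPS (7, 0), and 10 of 10 in SUR against CON (0, 0). For gene lists 2 of 10 reached 12 in LPS against CON (highest other 14, with CON 1, CON 3 and LPS 1 together; 11 among groupings that part every number pair). In SUR against LPS 3 of 10 reached 11 (highest other 15, LPS 1, SUR 1 and SUR 3; 7), and in SUR against CON 5 of 10 reached 8 (highest other 11, CON 1, CON 3 and SUR 1; 9). The highest other grouping joined the libraries numbered 1 in each comparison. Several of the other groupings do so by construction and the comparisons share libraries, so this alone says little about the structure of these samples. In SUR against CON a grouping that parts every number pair also reached more than the real one.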
